A study of Homo sapiens with 2 samples.

How the data were processed

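The data were 2 Affymetrix Human Gene 1.0 ST arrays, 1 hybridised with cDNA from ACHN cells carrying an shRNA against Kindlin-2 and 1 with cDNA from ACHN cells carrying a control shRNA. Both cultures were kept in medium with G418, a drug used to select transfected cells. Groups were taken from the shRNA label of each sample. With 1 array per group there was no replicate, so no p-value, standard error or count of significant genes could be given. The number of arrays, not the depth of a measurement, limits the precision of every value.

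The authors processed the arrays with RMA in Affymetrix Expression Console 1.4.1, per the submitters' processing notes. RMA corrects the background, makes the distributions of the arrays alike and summarises the probes of each transcript cluster, the array's unit for a gene. The deposited table held log2 values of 33297 transcript clusters, as judged from their range of 2.13 to 14.04. Which arrays were normalised together and which library file was used are not given in the sources used here. Scanner files were not used here, so the background correction and the probe summary could not be varied. The table carried no detection calls, and a low value therefore could not be separated into absent and dim. RMA compresses differences between dim values, which shrinks folds involving a dim value, whereas picking the largest folds of single arrays inflates them. Which of these weighs more could not be determined here. Of all transcript clusters, 475 (1.43%) had exactly the same value on both arrays.

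Gene symbols came from GEO's platform annotation and were updated through Entrez IDs to the RefSeq annotation of GRCh38.p14. A single symbol was given for 19460 transcript clusters, several symbols for 1754 and none for 12083. The Entrez ID was found for 19429 of the clusters with a single symbol, and the other 31 kept the platform's symbol. Clusters with several symbols or none were left out of the gene results. A gene with several clusters (769 of 18417 genes) was represented by the cluster with the highest mean value. A gene was kept when the higher of its 2 values was at or above 6.52, the median of all values in the table, which left 11822 genes. The build of the array's own annotation is not given in the sources used here, so no genome positions are printed. The RefSeq annotation served only for names, for the chromosome of a gene and for which genes neighbour each other.

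For each gene the difference was the Kindlin-2 shRNA value minus the control shRNA value on the log2 scale, and genes that differed by at least 2-fold were counted. For 34 gene lists written before the data were examined, the median difference of the members that passed the filter was set against the medians of 10000 random lists of the same size. The random lists were matched on mean value in 20 bins of equal size, and a list was set apart when its median lay outside their central 95%. The position among random lists describes these 2 arrays only. Genes of a pathway vary together, whereas the random lists draw genes one at a time, so a position outside the range is reached more easily than its percentage says. The spread of the difference was described in 10 bins of brightness and holds both array noise and real differences.

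The genes named in the text followed a rule fixed before the data were examined. It took FERMT2, the 12 genes with the largest positive and the 12 with the largest negative difference, and 18 genes fixed by name. It also took, from each list, up to 3 members per direction that differed by at least 1.5-fold. Small RNA genes, uncharacterised loci, open reading frames and olfactory receptor genes were left out of the 24 largest. Genes named outside the rule are marked as chosen after their values were seen.

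The counting and the list positions were tested on simulated data built from the 11822 genes of this comparison. A count at 2-fold recovered 98.0% of 100 genes changed by 3-fold and 8.0% of 100 genes changed by 1.5-fold, and it took in 8 unchanged genes. Of 200 unchanged lists of 30 genes, 2.0% lay outside the central 95%, and 99.0% of 100 lists shifted by 0.3 on the log2 scale lay above it. The simulated noise was normal, drawn for each gene alone, with its spread taken from these same 2 arrays. It held no heavy tails, differences between cultures, chromosome shifts or genes that vary together. The unchanged lists were random picks. These figures therefore check the procedure and are not error rates of the real counts or lists.

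The alternatives fixed before the data were examined were other fold thresholds (1.5 and 3), other filters on dim genes, a loess or median correction or a repeated quantile normalisation between the arrays, the mean over the clusters of a gene, the mean in place of the median of a list, and unmatched random lists. Subtraction of each autosome's median difference, or of the median difference of the 50 nearest measured genes on the same autosome, was added after the data were seen. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6.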

Results

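Gene expression was measured in ACHN cells, an established human renal carcinoma line that the labels describe as clear cell, after transfection with an shRNA against Kindlin-2 or a control shRNA. Kindlin-2, encoded by FERMT2, is an adaptor protein that binds the tails of beta integrins together with talin. The comparison asked which transcripts differ when Kindlin-2 is depleted. Each group held 1 array (n = 1), so all values below are single measurements without a replicate check, and the differences describe these 2 arrays. The middle of the values was alike on both arrays, with a median log2 value of 6.53 in the knockdown array and 6.51 in the control array. Across transcript clusters the arrays correlated with a Pearson r of 0.988, a figure over genes, which are not independent replicates. The SD of the log2 difference lay between 0.30 and 0.41 in all 10 bins of brightness.

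FERMT2 (transcript cluster 7979204) had a log2 value of 8.26 in the knockdown array and 9.37 in the control array. It was thus 2.16-fold lower in the knockdown array, at 46.4% of the control level, in the direction its label gives. Of the 11822 genes kept, 114 had a larger decrease. The other kindlins were dim: FERMT3 differed by -0.15 on the log2 scale and FERMT1, expressed in epithelia, by -0.58, or by -0.96 when the median of 50 neighbouring genes on chromosome 20 was subtracted. Integrin-linked kinase (ILK) differed by 0.24, and talin-1 (TLN1) by -0.51.

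In the knockdown array 167 genes were at least 2-fold higher and 149 at least 2-fold lower than in the control array, together 2.67% of the genes kept. The 12 genes with the largest positive difference began with the inward-rectifier potassium channel KCNJ15 (14.7-fold higher) and ANKRD1, an ankyrin repeat protein and known YAP target (13.6-fold higher). The membrane skeleton protein EPB41L3 was 7.32-fold higher, the protocadherin PCDH20 5.79-fold and the sialic acid-binding lectin SIGLEC15 5.46-fold. The neutrophil chemokine CXCL8 was 5.36-fold higher and the cyclic nucleotide phosphodiesterase PDE10A 5.26-fold. TNFRSF9, TNFAIP6, JADE3, MARCHF3 and GPC4 completed the set, between 4.68-fold and 5.06-fold higher.

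The largest decrease was that of the chemokine CXCL14, which was 16.99-fold lower in the knockdown array. Complement factor I (CFI) was 9.15-fold lower, ABCC9, a regulatory subunit of ATP-sensitive potassium channels, 8.96-fold, and cyclin D2 (CCND2) 7.41-fold. The transcription factor SIM1 was 6.25-fold lower and the prostacyclin synthase PTGIS 5.93-fold. The receptor FGFR2 was 5.70-fold lower, ANXA13 5.57-fold, argininosuccinate synthase (ASS1) 5.31-fold and the epithelial transcription factor ELF3 5.16-fold. SGPP2 and the glucose transporter SLC2A2 were 5.04-fold and 4.93-fold lower. In 9 of these 24 genes the lower value was under the filter floor of 6.52, among them ANKRD1, CXCL14, CFI and FGFR2. The same held for 95 of all 316 genes that differed by at least 2-fold. It also held for COL8A1, MMP7, TNFAIP3 and IFI44L, whose folds are given below. Cyclin D1 (CCND1), in contrast to cyclin D2, was 1.52-fold higher.

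**Figure D1:**
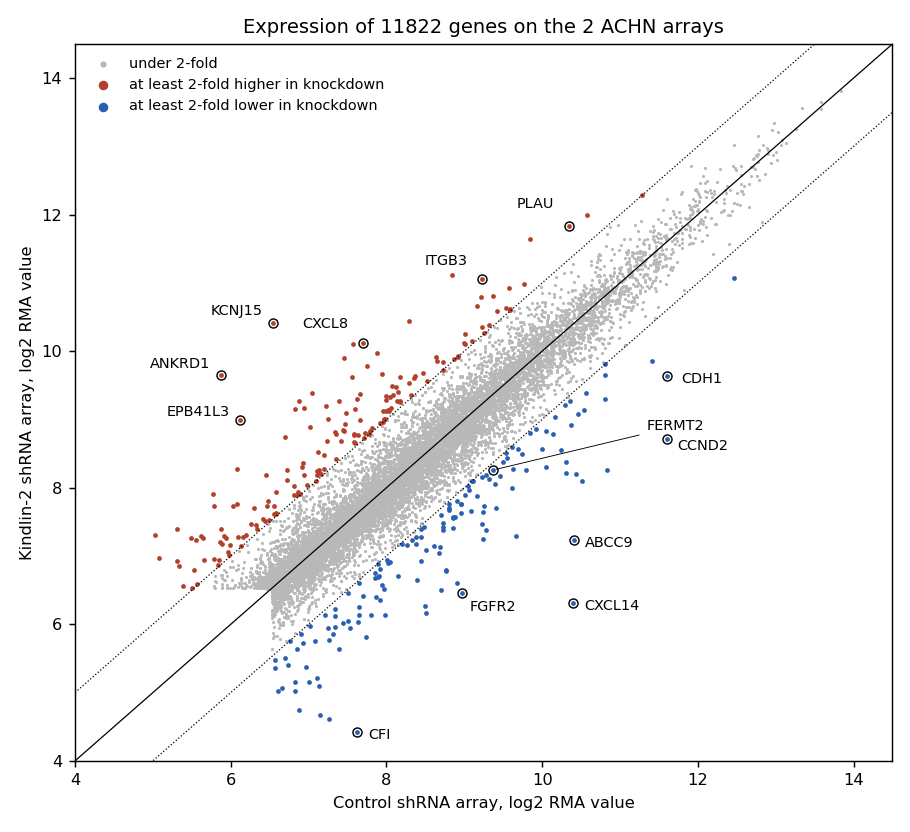
Log2 RMA value of each of 11822 genes (1 point per gene) on the control shRNA array (x axis) and the Kindlin-2 shRNA array (y axis), where the solid line marks equal values, dotted lines mark 2-fold and circled genes are named. The 167 red points are at least 2-fold higher and the 149 blue points at least 2-fold lower in the knockdown array, and FERMT2 lies just past the lower 2-fold line.

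Of the 34 gene lists, 12 had a median above and 8 a median below the central 95% of matched random lists, and 14 lay inside it. About 1.7 lists would lie outside if lists were random. The largest shift was in mitosis genes, which were higher in the knockdown array as a group. Of 39 measured members, 38 were above 0, 26 were at least 1.5-fold higher and 10 at least 2-fold higher, and none was 1.5-fold lower. Their median log2 difference of 0.80 lay above all 10000 random lists. The kinetochore protein NUF2 was 2.56-fold higher, the mitotic kinase AURKA 2.41-fold and its activator TPX2 2.26-fold. FOXM1, a transcription factor of this program and the only member below 0 (named after its value was seen), differed by -0.15. It lies on chromosome 12, whose genes had a median of -0.21, so its place below 0 is not separate from that shift. DNA replication and G1/S genes had a median of 0.47, also above all random lists, with 32 of 35 members above 0. The sliding clamp PCNA was 2.17-fold higher, the ribonucleotide reductase subunit RRM2 2.02-fold and GINS1 2.02-fold, while E2F8 was 1.54-fold lower. Replication-dependent histone genes had a median of 0.25, above 9999 of the random lists, and 1 of their 24 members, H2BC7, passed 1.5-fold. Several members, H2BC7 among them, lie close together on chromosome 6, so the 24 are not separate findings. AURKA, TPX2, PCNA and GINS1 lie on chromosome 20, whose genes were higher as a whole. With each autosome's median subtracted the median of the mitosis genes was 0.76.

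Integrin subunits differed in both directions. The beta-3 subunit ITGB3 was 3.55-fold higher in the knockdown array, the alpha-6 subunit ITGA6 2.45-fold and the alpha-4 subunit ITGA4 2.04-fold, while the beta-1 subunit ITGB1 differed by 0.46 on the log2 scale. The beta-4 subunit ITGB4, a hemidesmosome component, was 3.25-fold lower, ITGB8 2.01-fold and ITGB6 1.56-fold. Of 14 measured subunits 4 were at least 2-fold higher and 2 at least 2-fold lower, and the median of 0.43 lay above all random lists (0.27 with dim genes kept, still above the range). The adaptors of integrin adhesions had a median of -0.09, inside the range of random lists, but lay below it when the mean was used (-0.15) and when each autosome's median was subtracted (-0.11). Of 35 measured adaptors none was 2-fold higher and 2 were 2-fold lower, the tensins TNS1 (2.30-fold) and TNS3 (2.11-fold).

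The lists of matrix genes and of matrix proteases and their inhibitors were shifted upward by less. Extracellular matrix genes had a median of 0.17, above 9992 random lists, with 27 of 37 members above 0, and of 0.09 with dim genes kept, still above the range. Tenascin-C (TNC) was 4.07-fold higher, fibrillin-1 (FBN1) 3.66-fold and the collagen COL8A1 2.05-fold, whereas vitronectin (VTN) and nidogen-2 (NID2) were 2.29-fold and 2.13-fold lower. Matrix proteases and their inhibitors had a median of 0.15, above 9938 random lists, with 16 of 27 members above 0. Urokinase (PLAU) was 2.80-fold higher, the lysyl oxidase LOXL2 2.04-fold and the protease inhibitor SERPINE2 1.95-fold, and the matrilysin MMP7 was 3.01-fold lower. Lysyl oxidases are neither proteases nor their inhibitors. The list also holds LOX (0.33) and LOXL4 (0.24), named after their values were seen, and all of these lie above its median. The median therefore does not describe proteases and inhibitors alone. The gelatinases MMP2 and MMP9 did not pass the filter on dim genes, with differences of 0.06 and 0.33. The protease list moved inside the range when dim genes were kept.

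Epithelial junction and keratin genes were lower in the knockdown array, with a median of -0.44 below all 10000 random lists. Of 25 measured members 19 were below 0 and 10 were at least 1.5-fold lower. E-cadherin (CDH1) was 3.90-fold lower, the tight junction protein TJP3 1.87-fold, and the protease PRSS8 was 2.10-fold higher. The median was -0.13 when dim genes were kept. Mesenchymal markers and regulators of the epithelial-mesenchymal transition had a median of 0.01 and a mean of -0.05, inside the range, but 0.16 and above it when the median of 50 neighbouring genes was subtracted from each gene. N-cadherin (CDH2) differed by 0.01, vimentin (VIM) by 0.20, ZEB1 by 0.29 and SNAI2 by -0.64, while SNAI1, which did not pass the filter, differed by -0.35. Renal lineage and distal nephron genes had a median of -0.21, below 9858 random lists (-0.15 with dim genes kept, mean -0.34), with SALL1 2.15-fold and PAX2 1.58-fold lower. Proximal tubule markers had a median of 0.24 over 10 members, but GATM and DPP4 were 1.57-fold and 1.55-fold lower, and the list moved inside the range when dim genes were kept, when the mean was used and when neighbour medians were subtracted.

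Among the signalling lists, MAPK feedback and immediate early genes had a median of 0.20, above 9991 random lists, with 18 of 29 members above 0 and 11 below. The list joins feedback genes, ligands and immediate early genes, and the last differed in both directions. JUNB (-0.53) and FOS (-0.34) were lower and JUN (0.27) and ATF3 (0.28) higher (named after their values were seen). The median therefore does not describe immediate early genes alone. The ETS factor ETV4 was 2.32-fold higher and the phosphatase DUSP6 2.02-fold, while the immediate early gene EGR1 was 2.44-fold lower. Receptor tyrosine kinases and their EGF family ligands had a median of -0.26, below 9996 random lists, and it was -0.07 and inside the range with dim genes kept, and inside it with the mean. In this list ERBB3 was 2.58-fold lower beside FGFR2, and the ligands TGFA and EREG, which are also in the MAPK list, were 1.95-fold and 1.90-fold higher. YAP and TEAD targets had a median of 0.17, above 9956 random lists, but their members differed widely and the list was inside the range (0.10) when neighbour medians were subtracted and at 0.32 when the mean was used. ANKRD1 stood far above the rest, GGH was 2.63-fold and FJX1 2.32-fold higher, IGFBP3 was 2.32-fold lower, and the classical targets CCN1 and CCN2 differed by 0.01 and 0.16. Targets of TGF-beta (median 0.01), SRF and MRTF (0.03), Wnt and beta-catenin (-0.06) and p53 (0.05) lay inside the range, and the means of the SRF and TGF-beta lists had the opposite sign (-0.08 and -0.0046). In the TGF-beta list INHBA, an activin subunit (2.68-fold), SPHK1 (2.20-fold) and TGFB2 (2.15-fold) were higher and TNS1 lower by over 2-fold. In the SRF list MICAL2 was 2.02-fold higher and EGR1 lower, in the Wnt list only MMP7 passed 2-fold, and it was lower, and no p53 target did. MYC differed by -0.27.

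The medians of the cytokine list and of the interferon-stimulated list had opposite signs, but members of both went both ways. NF-kB targets, cytokines and chemokines had a median of 0.18, above 9973 random lists, with 16 of 25 members above 0 and 9 below. Interleukin-6 (IL6) was 3.22-fold and TNFAIP3 2.27-fold higher beside CXCL8. TNFSF10, the death ligand TRAIL, was 4.72-fold lower and CCL2 3.74-fold lower. This list was inside the range when dim genes were kept, with a median of 0.07, and when the mean was used, and was at 0.28 when neighbour medians were subtracted. Interferon-stimulated genes had a median of -0.35, below all random lists, with 24 of 34 members below 0. It was -0.22 with dim genes kept and -0.23 with neighbour medians subtracted, still outside the range. SAMD9 was 1.71-fold and IFI44L 1.66-fold lower, and HERC5 was 2.55-fold higher. Antigen presentation genes had a median of -0.32, below 9988 random lists, and the class II accessory genes HLA-DMA and HLA-DMB were 1.83-fold and 1.70-fold lower. TAP1 (1.63-fold lower) belongs to both lists, as do PSMB8 (-0.35) and PSMB9 (-0.43), named after their values were seen. Of the 14 antigen presentation genes measured, 9 lie on chromosome 6, all below 0 and all within 50 neighbouring genes (CFB to ANKS1A) that had a median of -0.19, and the other 5 had a median of 0.10. With neighbour medians subtracted, the list was at -0.10 and inside the range, so its shift is not separate from that of its region, although the neighbours include other members.

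Metabolic and stress genes also separated. Genes of cholesterol synthesis had a median of -0.47, below all random lists, and 17 of 19 members were below 0. HMGCS1, an early enzyme of the pathway, was 1.80-fold lower and TM7SF2 1.75-fold. Genes of fatty acid synthesis and lipid storage had a median of -0.30 (-0.20 with neighbour medians subtracted), also below all random lists, with the desaturase SCD 1.95-fold lower. Unfolded protein response and ATF4 targets had a median of 0.33, above all random lists, with 25 of 34 members above 0 and 9 below. The cystine transporter SLC7A11 was 2.78-fold higher, the chaperone CALR 1.93-fold and STC2 4.13-fold, but NUPR1 was 2.94-fold lower. The list joins chaperone genes and ATF4 targets, and the ATF4 targets differed in both directions. PHGDH (-0.25) and SLC7A5 (-0.31) were lower and MTHFD2 (0.78) and PPP1R15A (0.65) higher (named after their values were seen). The median therefore does not describe ATF4 targets alone. Hypoxia and HIF targets had a median of 0.24, above 9999 random lists, and PDK1, which inhibits pyruvate dehydrogenase, was 2.28-fold higher. STC2 is in both of these lists. Glycolysis enzymes (0.11), NRF2 targets (0.10), apoptosis regulators (0.08) and oxidative phosphorylation subunits (-0.12) lay inside the range. The last list was below it when each autosome's median (-0.11) or the neighbour medians (-0.12) were subtracted, and NRF2 targets were above it (0.15) with the latter.

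**Figure D2:**
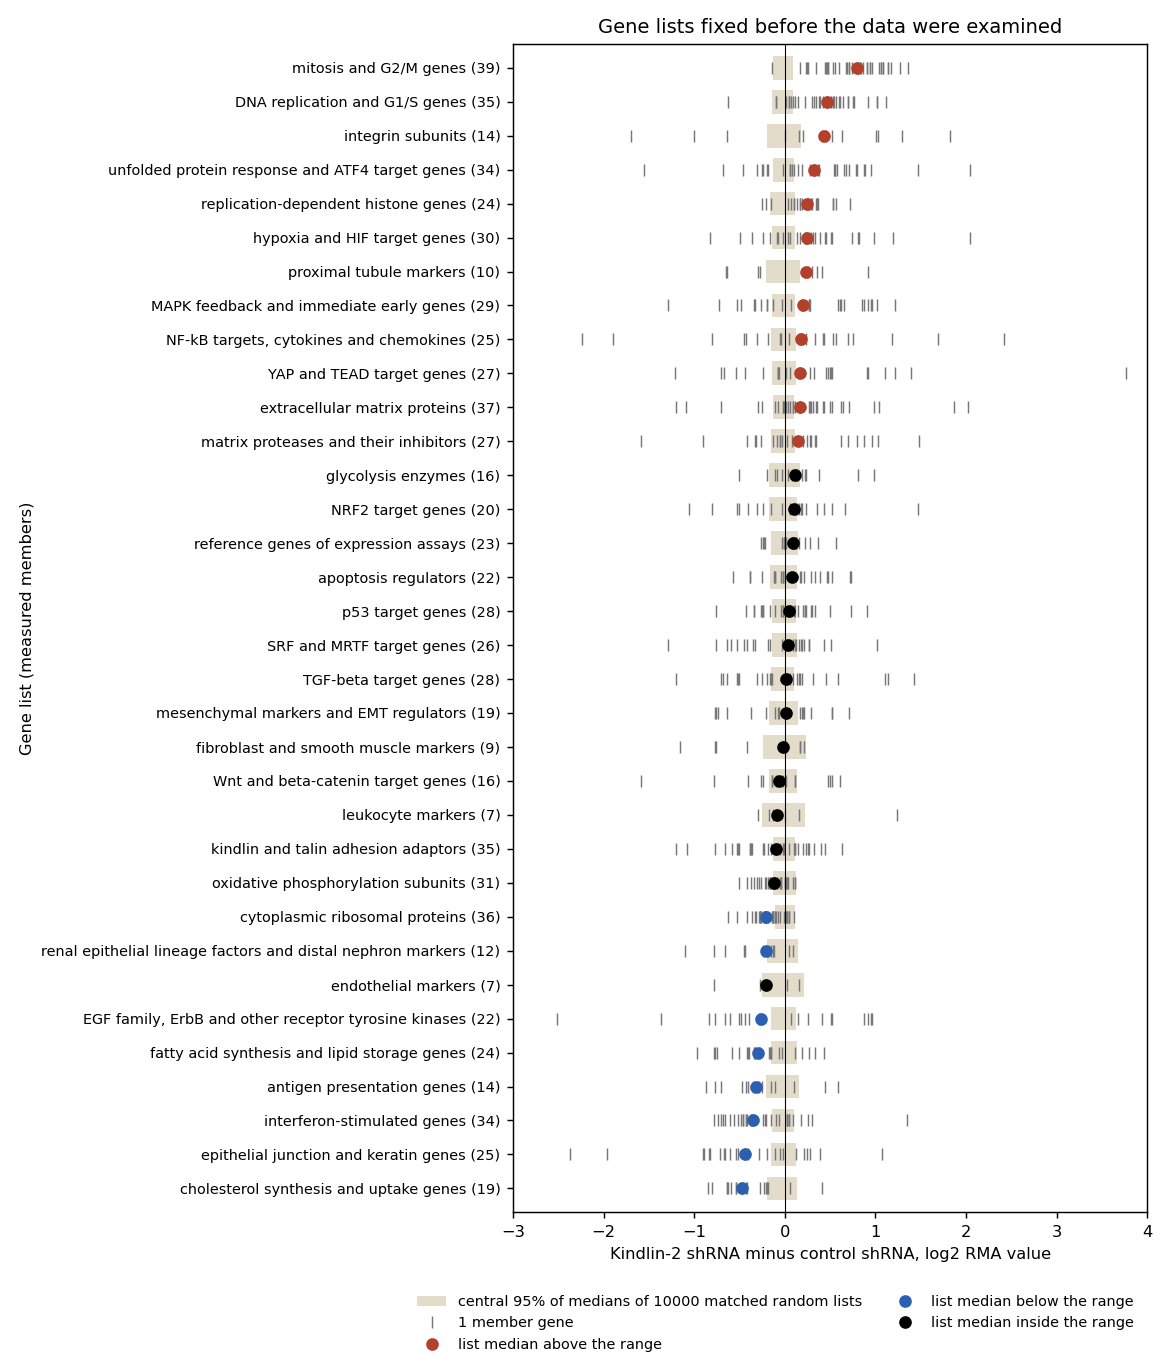
Kindlin-2 shRNA minus control shRNA on the log2 scale (x axis) for 34 gene lists (y axis, measured members in brackets), with a tick per member, a dot for the list median and a bar for the central 95% of medians of 10000 matched random lists. The median of the mitosis genes lies farthest to the right at 0.80 and that of the cholesterol genes farthest to the left at -0.47.

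Further lists described the sample rather than a pathway. Reference genes of expression assays had a median of 0.09 and none of 23 passed 1.5-fold. Cytoplasmic ribosomal protein genes had a median of -0.20, below 9998 random lists, with 30 of 36 below 0, and of -0.11 with neighbour medians subtracted, still below the range. Markers of other cell types that passed the filter were few. Fibroblast and smooth muscle markers (9 measured, median -0.02, mean -0.29), endothelial markers (7 measured, median -0.21) and leukocyte markers (7 measured, median -0.08, mean 0.10) lay inside the range, but endothelial markers were below it with dim genes kept (-0.14). CD68, which is also lysosomal, was 2.37-fold higher, and RGS5 was 2.24-fold lower.

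The differences were not spread evenly over the chromosomes. Genes of chromosome 9 had a median difference of -0.31 (495 genes), those of chromosome 7 -0.22 (551 genes) and those of chromosome 12 -0.21 (630 genes), while genes of chromosome 20 had a median of 0.26 (352 genes). The other 18 autosomes had medians within 0.1 of 0, but 10 of the 22 lay beyond all of their random gene sets, these 4 and chromosomes 1, 2, 3, 5, 13 and 19. A median near 0 can also cover opposite stretches. On chromosome 6, whose median was -0.04, 12 of 13 windows of 50 neighbouring genes from DUSP22 to COX7A2 were below 0 (lowest -0.25). All 9 from GCLC to GPR31 were above 0 (highest 0.24). The division at GCLC was placed where the sign changed, and consecutive windows share 25 genes, so these counts largely follow from that choice. Among the genes with the largest differences, ABCC9 and CCND2 lie on chromosome 12 and ASS1 on chromosome 9, in the direction of their chromosome's shift, and PTGIS lies on chromosome 20 against it. Of the other genes named so far, TNC and TLN1 lie on chromosome 9, and IL6, INHBA, ITGB8, TNS3, IGFBP3 and SAMD9 on chromosome 7. ERBB3, DUSP6 and FOXM1 lie on chromosome 12, and FERMT1, SNAI1, MMP9, AURKA, TPX2, PCNA and GINS1 on chromosome 20. FERMT2 lies on none of the 4, and differed by -1.19 with neighbour medians subtracted. A place off these 4 does not free a gene from a regional shift. Of 350 windows on the other autosomes, 9 lay beyond every window median of 100 shuffles of the differences over genes. Among them were windows at 0.22 on chromosomes 1 (INTS7 to SDE2), 2 (CWC22 to CFLAR) and 13 (NUP58 to WBP4). With each autosome's median subtracted, 162 genes were at least 2-fold higher and 131 at least 2-fold lower, and with neighbour medians subtracted 159 and 138.

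**Figure D3:**
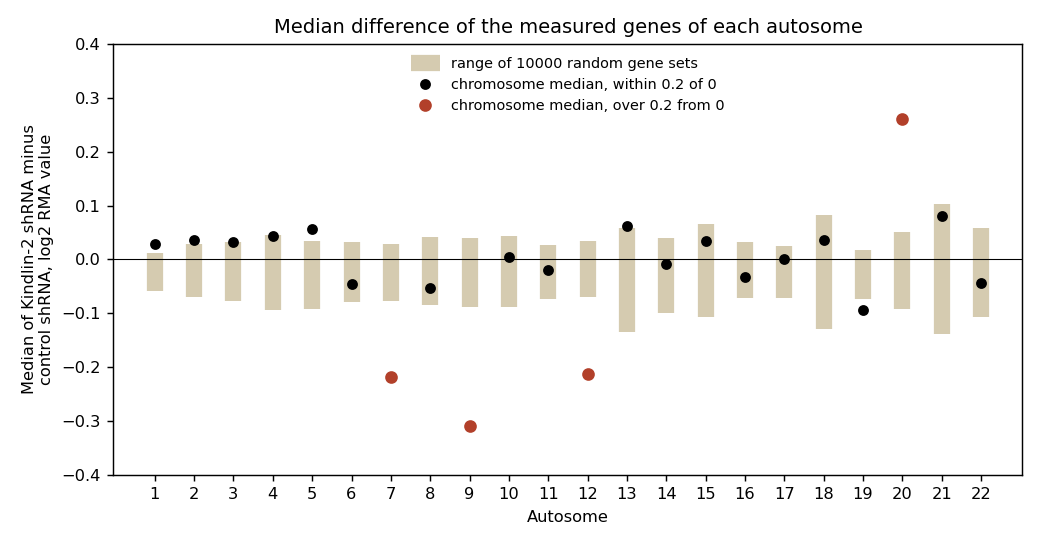
Median of Kindlin-2 shRNA minus control shRNA on the log2 scale (y axis) over the measured genes of each autosome (x axis), as dots, with bars for the range of medians of 10000 random gene sets of the same size matched on mean value. Chromosomes 7, 9 and 12 lie below -0.2 and chromosome 20 above 0.2.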

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

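Both results here concern transcript clusters that no gene result above used, though the array medians, the correlation and the spread by brightness took in all clusters, and they were set against the control array because no replicate exists. Among 3704 clusters with no gene listed that passed the filter on dim values, 61 were at least 2-fold higher and 19 at least 2-fold lower in the knockdown array than in the control array. Among 1098 clusters with several gene symbols, 13 were at least 2-fold higher and 10 at least 2-fold lower. These were 2.16% and 2.09% of the clusters of each kind, against 2.67% of the named genes, and none is named here. No group held the 4 arrays needed to look for a sample far from the others, and there was no second tissue, time or line in which to compare effects.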

How the results depend on the processing

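The number of genes past the threshold followed the threshold itself. At 1.5-fold, 603 genes were higher and 618 lower, and at 3-fold 40 and 44. Requiring the higher value to reach the 75th percentile of all values left 102 higher and 91 lower. Under the other filters, corrections between arrays and cluster rules the counts stayed between 121 and 186 higher and between 100 and 165 lower, within 1.5 times of 167 and 149. The FERMT2 difference ranged from -1.19 to -1.09. The number of lists outside the range of random lists lay between 17 and 22, and 14 of the 20 stayed outside on the same side in every alternative computed for lists. List positions were not computed under the 75th percentile filter or the other fold thresholds. With dim genes kept, the medians were -0.13 for epithelial genes, -0.22 for interferon-stimulated genes, -0.072 for receptor tyrosine kinases and 0.048 for proximal tubule markers. The last 2 were then inside the range, as were matrix proteases (0.08) and NF-kB targets (0.07), and endothelial markers (-0.14) were below it. With the mean in place of the median, YAP and TEAD targets were at 0.32 and fibroblast markers at -0.29. The mean also placed receptor tyrosine kinases, NF-kB targets and proximal tubule markers inside the range and adhesion adaptors (-0.15) below it. After subtraction of chromosome medians, added after the data were seen, adhesion adaptors (-0.11) and oxidative phosphorylation subunits (-0.11) were below the range. A second subtraction added then, of the median of 50 neighbouring genes from each gene, brought antigen presentation genes to -0.105 and YAP and TEAD targets (0.10) and proximal tubule markers (0.15) also inside the range. It placed oxidative phosphorylation subunits (-0.12) below the range and mesenchymal markers (0.16) and NRF2 targets (0.15) above it. For these changed positions the cause was not tested. Of the 142 other named genes, 3 moved by more than the SD of differences at their brightness in any of 6 alternatives, all when neighbour medians were subtracted, FERMT1 on chromosome 20 to -0.96, and CDKN2B and VLDLR on chromosome 9, list members not named above, to -0.32 and -0.31. No paired analysis was possible because each group holds 1 array, and for the same reason no replicate could be left out. The lack of replicates and of detection calls limits every difference.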

Other observations

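In 4 smaller gene families, listed after the data were seen, most measured members lay on one side of 0, though each family had members on the other side and no member passed 2-fold. As the families were chosen for their values, no position among random lists is given. Metallothioneins, which bind zinc and copper, were higher in the knockdown array in 7 of 8 measured genes, with a median log2 difference of 0.35, and MT1X differed by 0.67. Their sequences are similar enough for probes to be shared, so the single genes are uncertain. All 8 also lie side by side on chromosome 16, among 50 neighbouring genes (KRABD5 to NUP93) that had a median of 0.20 with them included, so they are not 8 separate findings. Nucleoporins had a median of 0.24 with 21 of 27 above 0, and cytosolic heat shock proteins and co-chaperones a median of 0.24 with 15 of 21 above 0, DNAJB4 (0.88) and HSPH1 (0.73) leading. Aldehyde dehydrogenases had a median of -0.32 with 10 of 13 below 0, with ALDH1A1 at -0.92 and ALDH2 at -0.90, but these lie on chromosomes 9 and 12, whose genes were lower as a whole.

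Of the tests that follow, the shares of genes and windows by chromosome and the statements on growth state were chosen after the result was seen, and the subtraction of chromosome medians was itself added then. The shift of whole chromosomes is the pattern most in need of a second look. On chromosome 9, 83.8% of measured genes were below 0, on chromosome 7 78.2% and on chromosome 12 76.3%, the smallest share of the 4, while 81.3% of genes on chromosome 20 were above 0. These shares largely follow from picking the chromosomes by their medians and add no support. That a few strongly changed genes do not account for the shift rests on the medians alone, since a median over at least 352 genes hardly moves with a few of them. After loess between the arrays the smallest of the 4 medians was still 0.21 from 0, and loess changed no gene kept by more than 0.05, so a trend with brightness is too small to account for it. All 76 windows of 50 neighbouring genes on these chromosomes (100%) had a median on the shifted side, but this nearly follows from picking the chromosomes by their medians and cannot decide between causes. A different copy number of these chromosomes in the control and knockdown cultures, which were kept in a selecting drug, could give such shifts, and so could broad regulation, and no DNA was measured to tell them apart.

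The higher mitosis genes are the largest shift among the fixed lists. Neither a brightness trend nor the shifts of the members' own chromosomes account for it directly. Loess changed the differences of the genes kept by only -0.05 to 0.03, so the trend is too small, and the median was 0.79 after it. It was 0.76 after chromosome medians were subtracted. The largest upward chromosome median was 0.26, so that subtraction could not have brought 0.80 into the range. Indirect effects of a chromosome difference between the cultures would remain after it, so it cannot speak to them. The growth state of the single culture harvested per group may still be the source, since the difference of 0.80 has no spread between cultures to be set against. An effect of the shRNA and a difference in density, growth or chromosome copy number between the 2 cultures cannot be told apart here.

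The lower epithelial genes remained at a median of -0.47 after loess and -0.33 after chromosome medians were subtracted. Neither a brightness trend nor the shifts of the members' own chromosomes therefore account directly for the whole of it. The subtraction cannot speak to indirect effects of a chromosome difference between the cultures. As with the mitosis genes, the growth state or chromosome copy number of the 1 culture per group could be the source of the difference of -0.44. Neither can be told apart from an effect of the shRNA. Whether a second shRNA against Kindlin-2 gives the same picture was not tested.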
